A study of Mus musculus with 8 samples.

How the data were processed

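The series holds 8 Affymetrix whole-transcript GeneChip arrays, 1 per mouse, of germinal centre B cells sorted 7 days after immunisation from 4 control and 4 LRF knockout mice. Per the labels, RNA was isolated with a microprep kit, ribosomal RNA was reduced and the RNA was amplified in a 2-cycle protocol before hybridisation. The deposited values are log2 values that the authors made by RMA in Affymetrix Expression Console, with no version given, which covers background correction, normalization between arrays and summary of probes into probe sets. The log2 scale was checked on the values, whose array medians were 7.25 ± 0.01 in controls and 7.34 ± 0.04 in knockouts (SD, n = 4 each). Arrays have no count depth, and precision is limited by the number of arrays. Samples were grouped by the stated genotype, and replicates keep the numbers of the labels, 1, 2, 3 and 5 for controls and 1 to 4 for knockouts.

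Of 35556 probe sets, 23410 were in the probe-to-gene table used, 21789 with 1 gene symbol and 1621 with several, and 12146 were not listed. Probe sets with 1 symbol were analysed, and for the 999 genes with several such probe sets the one with the highest mean over the 8 arrays was taken, which gave 19938 genes. Gene identifiers matched a reference gene table for 21698 of the 21789 probe sets, and 0 symbols needed an update. No filter on low values and no further normalization were applied. Genes without a probe set of their own symbol alone, such as Aicda, Cdkn1a and Cd19, were not analysed here.

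Knockout minus control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. SE values are the moderated ones of limma. Equal replicate numbers were not stated to mark pairs, so the main fit was planned without a block. Deviations from the group means were also correlated, across genes, between control and knockout arrays. The correlations were 0.08, −0.12 and −0.00 for arrays of equal number and −0.21 to 0.18 for arrays of unequal number. These values do not exclude pairing. Zbtb7a, array medians and list means were compared by exact two-sided permutation over the 70 relabellings of the 8 arrays. Log2 fold changes in the text are knockout minus control.

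The analysis settings, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Of 35 gene lists, which hold 676 distinct genes of which 593 were measured, 34 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The sex-linked transcripts were too few and are described singly. Members were also adjusted over the list alone. Some genes stand in several lists. Named genes are Zbtb7a and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap. Gene segments of antigen receptors, predicted genes and Rik names were skipped, which passed over 120 changed genes that were higher. From each called list up to 4 members of smallest p are named, and from each other list up to 3. Genes within 10 Mb of Zbtb7a were compared with all others by a two-sided Fisher's exact test, over the 19856 genes with a position.

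The alternative settings fixed in advance were a filter on the lowest 40% of genes, the mean of a gene's probe sets, every probe set singly, quantile normalization applied again, centring on array medians, eBayes with trend and robust, array weights, a replicate block, an adjusted p threshold of 0.10, each array left out, an estimated correlation, a preset correlation of 0.05, the set test fry, windows of 5 and 20 Mb and an unadjusted p for the genes in the window. Chosen after the values were seen were the removal of the intensity trend (a lowess curve of span 0.3 of each array's deviation from the gene means, subtracted), alone and with an estimated correlation, a block for the arrays with high Xist, knockout replicate 3 alone against the controls, each array left out for the monocyte genes, draws and regions for the 5 Mb window, a division of the dark zone list by the genes it shares with the G2 to M list, and a background matched on expression.

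The procedure was tested on simulated data, 20 runs with 200 changed genes each. It recovered 28.4% of genes changed by 0.3 on the log2 scale, 87.0% at 0.6 and 98.2% at 1, and 5.01% of its calls were false. With no change it called 0 genes and 0 lists, and a list shifted by 0.2 was called in 100% of runs. The simulated genes varied independently of each other. In the data the estimated correlation was 0.50 in the ribosomal protein list and 0.64 in the G2 to M list. The simulated shares therefore do not show how often correlated genes and lists are called falsely. The intensity trends of the arrays, simulated without any changed gene, led to a mean of 19.25 called lists (16 to 22) and 0.05 called genes, and to 0 of either after the trend was removed.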

Results

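Gene expression was measured in germinal centre B cells of 8 mice, 4 controls and 4 in which B cells lacked LRF, the transcription factor encoded by Zbtb7a. Germinal centres are the sites in lymphoid tissue where B cells that have met an antigen divide, mutate their antibody genes and are selected. The mice were 10 weeks old and of mixed genetic background, and had been immunised with sheep red blood cells 7 days before the cells were sorted as B220 and CD19 positive, CD38 negative and Fas positive. All mice expressed Cre recombinase under the mb-1 (Cd79a) promoter, which is active in B lineage cells. The knockouts carried 2 conditional Zbtb7a alleles and the controls 1, so that the controls were heterozygous. Total RNA of each mouse was hybridised to 1 Affymetrix array, and the values were log2 RMA values of 35556 probe sets. The comparison asked how the expression profile of germinal centre B cells without LRF differed from that of cells with 1 intact allele, and its precision is limited by the 4 arrays per group.

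Zbtb7a itself was lower on every knockout array than on every control array. Its single probe set had a mean of 7.82 ± 0.10 (SD, n = 4) in controls and 7.30 ± 0.05 (SD, n = 4) in knockouts. The log2 fold change was −0.51 (SE 0.07, limma adjusted p = 0.000944), a level 1.43-fold lower. The exact two-sided permutation p was 0.0286, the smallest that 70 relabellings can give. Where the probes of this set lie relative to the deleted part of the gene is not given in the sources used here, so the remaining signal does not measure remaining intact transcript.

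Of 19938 genes tested, 2784 changed in the knockout cells, 1312 higher and 1472 lower. Most changes were small: the median absolute log2 fold change of the changed genes was 0.32, 143 of them reached 0.58 and 8 reached 1. The groups did not overlap for 4035 genes, 20.2% of those tested against 2.86% by chance, and 2376 of these genes were among the changed ones. Leaving out 1 array at a time gave 1376 changed genes without control replicate 2, 1713 without control replicate 5, 1622 without knockout replicate 1, 1149 without knockout replicate 2, 1374 without knockout replicate 4 and 5350 without knockout replicate 3. When each array was centred on its median, the total was 2735 but the division was 401 higher and 2334 lower.

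The largest rise was that of Zbtb10, a zinc finger gene of the same family as Zbtb7a, from 6.82 ± 0.07 to 8.18 ± 0.24 (SD, n = 4 each), a 2.56-fold higher level (log2 fold change 1.36, SE 0.10, adjusted p = 1.85e-05). Tmeff1, which encodes a transmembrane protein with follistatin-like domains, was 2.49-fold higher (1.32, SE 0.10), and Adcy6, an adenylyl cyclase, was 2.21-fold higher (1.14, SE 0.08). Zc3h12c, a CCCH zinc finger gene of the regnase family, was 2.17-fold higher and Ace, the angiotensin-converting enzyme, 2.01-fold higher. Lyz2, the lysozyme gene of myeloid cells, rose 1.95-fold, from 8.21 ± 0.44 to 9.17 ± 0.31 (SD, n = 4 each). Bhlhe41, a transcriptional repressor characteristic of B-1 cells, rose 1.82-fold (log2 fold change 0.86, adjusted p = 0.00386). The other genes among the 12 with the largest rise were Ssxb5, Olfr164, Ffar3, a receptor for short-chain fatty acids, Epb41l5 and Mex3a, with log2 fold changes from 0.83 to 0.92. Ssxb5 had the lowest control level of the 12, 3.48 ± 0.33.

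The largest fall was that of Akip1, which encodes a protein kinase A interacting protein, from 8.60 ± 0.05 to 7.37 ± 0.27 (SD, n = 4 each), a 2.35-fold lower level (log2 fold change −1.23, SE 0.11, adjusted p = 7.60e-05). Zdhhc2, a palmitoyltransferase, was 2.20-fold lower, and Fads2, a fatty acid desaturase, was 2.11-fold lower (−1.08, SE 0.11, adjusted p = 0.000217). Osbpl9, an oxysterol-binding protein, fell from 10.55 ± 0.07 to 9.65 ± 0.16, the change with the highest control level of the 12. Hmgn5, a nucleosome-binding protein, fell by 0.88 log2 and Rgs18, a regulator of G protein signalling, by 0.86. Cyp39a1, an oxysterol hydroxylase, had a log2 fold change of −0.83, Mrps26, of the mitochondrial ribosome, −0.81, and Cpm, a membrane carboxypeptidase, −0.80. Mir680-1, Anp32-ps and Smagp completed the 12, at −0.85, −0.82 and −0.80. These 24 genes kept their direction in every setting tried, and 16 of them lost their call in at least 1 setting. Of the 16, Lyz2 lost it in 3 settings, Anp32-ps in 2 and each of the others in 1.

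**Figure D1:**
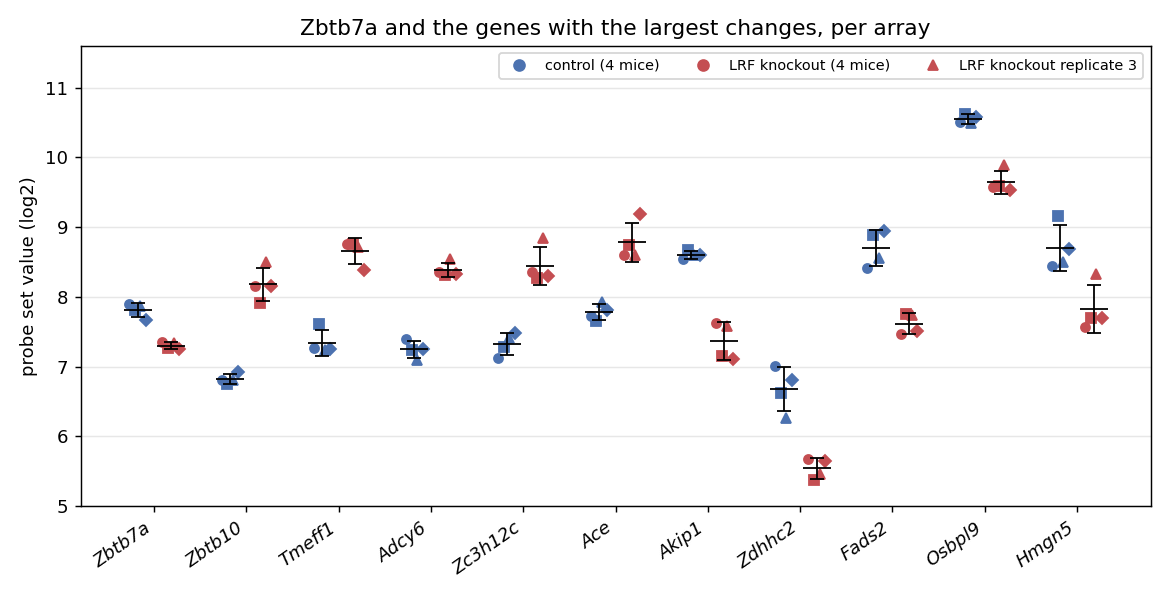
Probe set values (log2, vertical axis) of Zbtb7a, the 5 genes with the largest rise and the 5 with the largest fall (horizontal axis) on the 4 control and 4 LRF knockout arrays. Points are single mice with a symbol for each replicate within its group, and bars are mean and SD. For each of the 11 genes the points of the groups do not overlap, as for Zbtb7a with means of 7.82 and 7.30.

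The knockout arrays also differed from the control arrays across the whole range of expression, so called lists are given below with and without this difference. Genes were divided by mean expression into 10 bins of equal size. The median log2 fold change was 0.08 in the lowest bin, 0.11 in the third and −0.16 in the highest. Knockout replicates 1, 2 and 4 lay 0.07, 0.14 and 0.12 below the gene means in the highest bin, whereas replicate 3 lay 0.03 above them and the controls 0.06 to 0.09 above. The array median was 7.25 ± 0.01 in controls and 7.34 ± 0.04 in knockouts (SD, n = 4 each, exact permutation p = 0.0286). With this intensity trend subtracted from each array, a setting chosen after the values were seen, 1652 genes changed, 682 higher and 970 lower, 1279 of them shared with the 2784 in the same direction. All 24 genes of largest change still passed.

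**Figure D2:**
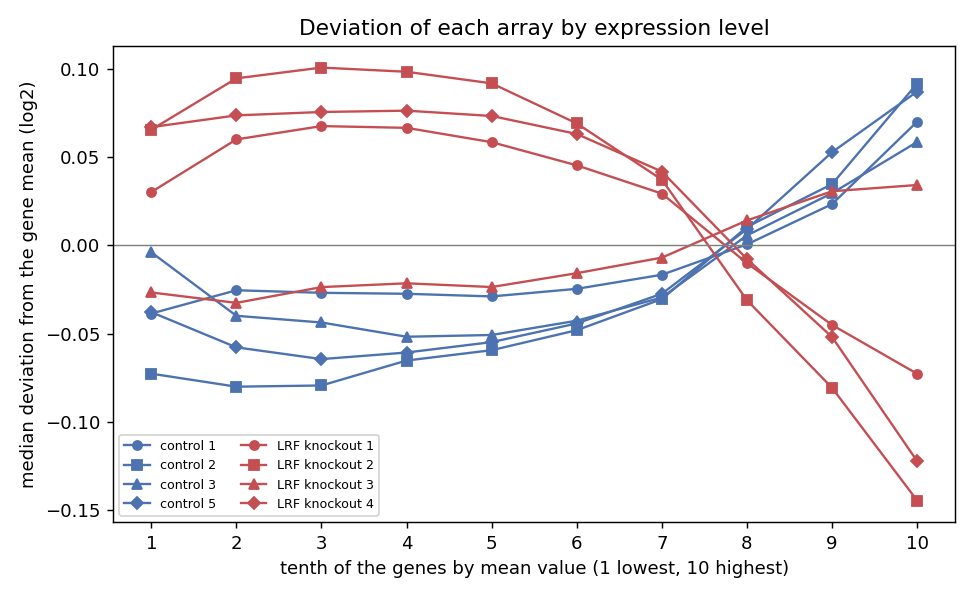
Median deviation of each array from the gene means (log2, vertical axis) in 10 bins of the 19938 genes ordered by mean value (horizontal axis), with a line per array, controls blue and LRF knockouts red. In the highest bin, knockout replicates 1, 2 and 4 lie at −0.07, −0.14 and −0.12, knockout replicate 3 at 0.03 and the controls at 0.06 to 0.09.

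Gene lists fixed before the data were examined were tested against the other genes with camera at a preset inter-gene correlation of 0.01. Of 34 lists, 16 were called, 14 lower and 2 higher, and none was called when the correlation was estimated from the data. With the intensity trend removed 11 were called, 7 lower and 4 higher, and 9 of these were among the 16. In simulated data the array trends alone called 16 to 22 of the 34 lists, so the camera result is given for each called list with and without the trend. Random lists matched on expression had a median of −0.16 for the B cell receptor list, whose own was −0.10. For the germinal centre identity list it was −0.18 against −0.20. The ribosomal protein list had −0.38 against −0.18 in matched lists, and the oxidative phosphorylation list −0.29 against −0.09. Quantile normalization applied again ended the same 7 calls as removing the trend, and the medians of the B cell receptor, unfolded protein response and immunoglobulin diversification lists were then above 0 (0.02, 0.02 and 0.03). Leaving out the lowest-expressed 40% of genes ended the calls of the glycolysis, unfolded protein response, follicular helper T cell contact, immunoglobulin diversification and NK cell lists. The NK cell list had a mean level of 6.10, and the filter removed members such as Klrd1, Gzmb, Gzma and Ncr1. Its lost call therefore does not test the list as a whole.

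Genes of protein synthesis and mitochondrial respiration were lower in the knockout cells. Of 26 cytosolic ribosomal protein genes measured, 17 fell and none rose (21 fell when adjusted over the list alone), with a median log2 fold change of −0.38 (camera adjusted p = 3.72e-14; adjusted p = 0.311 with an estimated correlation). Rpl5 had −0.68 (SE 0.13, adjusted p = 0.00524), Rpl7 −0.57, Rps3 −0.55 and Rps14 −0.52. Of 27 oxidative phosphorylation genes, 15 fell and none rose (22 when adjusted over the list alone), with a median of −0.29 (camera adjusted p = 9.03e-14; adjusted p = 0.282 with an estimated correlation). Among them were Ndufb5 of complex I (−0.52), Uqcrc1 of complex III (−0.49), and Atp5c1 (−0.52) and Atp5a1 (−0.48) of the ATP synthase. Both lists were still called lower with the intensity trend removed, at medians of −0.18 and −0.22 and camera adjusted p of 0.000752 and 5.75e-07, with 5 ribosomal protein genes and 7 oxidative phosphorylation genes still lower and 1 ribosomal protein gene higher. Rps14 (adjusted p = 0.0664) and Atp5a1 (adjusted p = 0.0579) no longer passed. Knockout replicate 3 had list means of 10.64 and 9.29, below the lowest controls at 10.84 and 9.45.

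Genes of sterol and fatty acid synthesis were also lower: 7 of 19 fell, the same number when adjusted over the list alone, and none rose (median −0.13, camera adjusted p = 2.66e-06; adjusted p = 0.311 with an estimated correlation). Idi1 (−0.69, SE 0.11), Cyp51 (−0.68, SE 0.09), Insig1 (−0.54) and Sqle (−0.52), of the cholesterol pathway and its regulation, fell by more than the list's median and passed with the trend removed as well. The list was then still called (camera adjusted p = 0.00839), at a median of −0.06. On the deposited values 10.2% of random lists matched on expression had a lower median. The glycolysis list was called lower (median −0.17, camera adjusted p = 0.00292; adjusted p = 0.311 with an estimated correlation), with 2 of 15 genes lower, Hk1 (−0.38) and Tpi1 (−0.37), and 1 higher, Hk2 (0.30). Adjusted over the list alone, 4 fell and 1 rose. None of these 3 passed with the trend removed and the call ended (adjusted p = 0.961), with the median at −0.00 and the test's direction turned to higher. The 20 measured genes of the unfolded protein and amino acid stress response had 3 lower, Atf4 (−0.33), Asns (−0.49) and Phgdh (−0.30), or 5 when adjusted over the list alone (median −0.10, camera adjusted p = 0.00636; adjusted p = 0.311 with an estimated correlation). The call of this list ended with the trend removed (adjusted p = 0.759), and Asns alone still passed. The MYC-driven ribosome biogenesis list was not called (camera adjusted p = 0.103), although Myc itself rose (0.27, adjusted p = 0.0427) and Odc1 (−0.36) and Ncl (−0.38) fell, with 1 rising and 3 falling when adjusted over the list alone. It was called lower without control replicate 3 (median −0.08) or knockout replicate 3 (median −0.09), and of the 3 genes Myc alone passed with the trend removed.

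Genes of mitosis were lower. Of 33 genes of the G2 to M phases, 11 fell and none rose (15 when adjusted over the list alone), with a median of −0.24 (camera adjusted p = 7.98e-11; adjusted p = 0.315 with an estimated correlation). Mad2l1 (−0.48) and Bub3 (−0.42) of the spindle checkpoint, Cdca8 (−0.41) and Nuf2 (−0.41) of the chromosomal passenger complex and the kinetochore were the members of smallest p. The list was still called with the trend removed (median −0.16, camera adjusted p = 0.000204), when 3 genes passed and Mad2l1 and Nuf2 did not. Knockout replicate 3 had a list mean of 9.38, equal to the control mean of 9.38 ± 0.09, and the mean of all 4 knockouts was 9.15 ± 0.16 (SD, n = 4, exact permutation p = 0.0857). Of 14 replication-dependent histone genes, 6 fell (7 when adjusted over the list alone), H4c6 with −0.60 and H4c3 with −0.43 among them (median −0.24, camera adjusted p = 1.53e-06; adjusted p = 0.311 with an estimated correlation; 0.00596 with the trend removed). Of 29 genes of the G1 to S phases, 4 fell, Rrm1 (−0.41), Chaf1b (−0.38), Prim1 (−0.37) and Tyms (−0.31), or 8 when adjusted over the list alone (median −0.16, camera adjusted p = 5.51e-05; adjusted p = 0.427 with an estimated correlation). None of the 29 passed with the trend removed, and the call ended (adjusted p = 0.416).

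Cell cycle inhibitors moved both ways, and the list was not called (camera adjusted p = 0.279). Cdkn2b, which encodes the CDK4 and CDK6 inhibitor p15, rose 0.64 (SE 0.08, adjusted p = 0.000754), whereas Cdkn2c, encoding p18, fell by 0.55 and Rbl1, the retinoblastoma relative p107, fell by 0.71. In all, 3 of 13 rose and 2 fell, against 3 and 4 when adjusted over the list alone. Of 25 p53 target genes, 3 rose and none fell: Zmat3 (0.82, SE 0.10, adjusted p = 0.000383), Ccng1 (0.40) and Pmaip1 (0.32), a proapoptotic gene. The list was not called (median 0.14, camera adjusted p = 0.119), and 7 rose and 2 fell when adjusted over the list alone. Without knockout replicate 1 it was called higher (median 0.15). Cdkn1a had only a probe set with several gene symbols and was not analysed here. Of 14 BCL2 family genes, 3 rose and 2 fell, Bak1 (−0.47) and Mcl1 (−0.33), against 4 and 2 when adjusted over the list alone. The median was 0.09 while the test pointed lower, and the list was not called (camera adjusted p = 0.908). Mcl1 no longer passed with the trend removed (adjusted p = 0.321).

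Among genes of the germinal centre programme, dark zone-associated genes were lower: 9 of 16 fell, also when adjusted over the list alone, with Cxcr4 (−0.45, SE 0.08), the chemokine receptor that holds cells in the dark zone, Plk1 (−0.42), Tcf3 (−0.39), which encodes the E protein E2A, and Cenpa (−0.33). The list had a median of −0.29 (camera adjusted p = 3.17e-06; adjusted p = 0.311 with an estimated correlation). With the trend removed it remained called (median −0.22, adjusted p = 0.0363), but none of its genes passed as lower and 1 passed as higher. Of the 16 genes, 7 also stand in the G2 to M list, and the other 9, separated after the values were seen, were lower on the deposited values (camera p = 0.00182; p = 0.0789 with an estimated correlation) but did not pass with the trend removed (camera p = 0.282). On knockout replicate 3 the median of the 16 was −0.07. Aicda, of both the dark zone and identity lists, was not analysed here. Of 21 germinal centre identity genes, 6 fell (12 when adjusted over the list alone), led by Nuggc (−0.72, SE 0.08, adjusted p = 0.00034), with Efnb1 (−0.30), Spib (−0.28) and Ezh2 (−0.33). The list was called lower at a median of −0.20 (camera adjusted p = 3.98e-08; adjusted p = 0.282 with an estimated correlation), and with the trend removed its median was 0.00 with the test still pointing lower, its call ended (adjusted p = 0.745), and 1 gene of the list passed as higher and 1, Nuggc, as lower. Light zone-associated genes moved both ways, with 3 of 22 higher and 4 lower, or 4 and 6 when adjusted over the list alone, and a median of 0.01 while the test pointed lower (camera adjusted p = 0.141). Ccnd2, encoding cyclin D2, rose 0.57 (adjusted p = 0.000963), while Gadd45b (−0.75, SE 0.10) and Cd69 (−0.51) fell, and all 3 passed with the trend removed.

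Genes of antigen presentation by MHC class II were lower: 8 of 13 fell and none rose (9 when adjusted over the list alone; median −0.38, camera adjusted p = 3.98e-08; adjusted p = 0.282 with an estimated correlation). H2-Oa, part of the H2-O complex that modulates peptide loading, had −0.76 (SE 0.10, adjusted p = 0.000884), and the class II chains H2-Ab1, H2-Aa and H2-Eb1 had −0.47, −0.47 and −0.46. It was still called with the trend removed (median −0.14, adjusted p = 0.013), H2-Oa and H2-Aa passed, and H2-Ab1 and H2-Eb1 did not. Of 24 genes of B cell receptor signalling, 9 fell (10 when adjusted over the list alone), among them Dok3 (−0.67, SE 0.09), Blk (−0.51), Vav1 (−0.44) and Cd79a (−0.34) (list median −0.10, camera adjusted p = 2.66e-06; adjusted p = 0.311 with an estimated correlation). With the trend removed the median of this list was 0.04, the test pointed higher and its call ended (adjusted p = 0.846), and 3 of its genes passed as higher and 4 as lower, Dok3, Blk and Vav1 among the latter. Of 16 molecules through which B cells meet follicular helper T cells, Icosl (−0.42), Cxcr5 (−0.40) and Cd84 (−0.37) were lower and Cd80 (0.35) was higher, with 4 lower and 1 higher when adjusted over the list alone (median −0.13, camera adjusted p = 0.00167; adjusted p = 0.311 with an estimated correlation). That call ended with the trend removed (adjusted p = 0.416), as did those of Cxcr5 and Cd80. Of 18 measured genes in the list named immunoglobulin diversification and mismatch repair, 4 fell, Hmces (−0.67), Polh (−0.38), Apobec1 (−0.33) and Xrcc6 (−0.29), and 1 rose, or 5 and 1 when adjusted over the list alone (median −0.06, camera adjusted p = 0.0278; adjusted p = 0.544 with an estimated correlation). This call ended with the trend removed (adjusted p = 0.702), as did those of Polh and Apobec1. It also ended without control replicate 5, knockout replicate 2 or knockout replicate 4 (medians −0.05, −0.05 and −0.03).

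Genes of the plasma cell programme were higher in part. Of 24, 8 rose and none fell (8 and 1 when adjusted over the list alone), including the regulators Irf4 (0.51, SE 0.09, adjusted p = 0.00346) and Prdm1 (0.51, SE 0.09, adjusted p = 0.00384), which encodes Blimp-1, and Slpi (0.42). The list was not called on the deposited values (median 0.10, camera adjusted p = 0.103). With the trend removed it was called higher (median 0.20, adjusted p = 1.44e-05; adjusted p = 0.6 with an estimated correlation). On the deposited values the list mean was highest on knockout replicate 3, at 9.20 against 8.86 to 8.92 in controls. Knockout replicate 4 lay among the controls at 8.90, and the exact permutation p of the list mean was 0.0571. The list was called higher on these values without control replicate 2, knockout replicate 1 or knockout replicate 4 (medians 0.09, 0.12 and 0.14). Of 17 marginal zone and B-1 cell genes, 5 rose and 1 fell, or 7 and 2 when adjusted over the list alone: Asb2 had 0.47 and S1pr3 0.32 beside Bhlhe41 (list camera adjusted p = 0.238). Naive and memory B cell genes moved both ways (4 of 22 higher and 5 lower, also when adjusted over the list alone; camera adjusted p = 0.18), with Gpr183, a receptor for oxysterols that guides B cells to the follicle edge, higher (0.43) and Ms4a1, which encodes CD20, lower (−0.37). Ms4a1 no longer passed with the trend removed (adjusted p = 0.128). Of 25 measured genes in the Notch signalling list, Notch3 (0.33) rose and Cr2 (−0.34) fell. Cr2 also stands in the naive and memory list and in the marginal zone and B-1 list. Dtx1 had −0.22 without passing (adjusted p = 0.0537), and 1 rose and none fell when adjusted over the Notch list alone. The list was not called (median 0.11, camera adjusted p = 0.238) but was with the trend removed (median 0.09, adjusted p = 0.0363; adjusted p = 0.673 with an estimated correlation), where neither Notch3 (adjusted p = 0.0528) nor Cr2 (adjusted p = 0.251) passed.

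Genes reported as targets of LRF did not move together: of 12 measured, Cdkn2a, which encodes p16 and p19Arf, was higher (0.28, SE 0.08, adjusted p = 0.0376) and the embryonic globin gene Hbb-bh1 was lower (−0.45, adjusted p = 0.00725). Hbb-bh1 had a low level, 6.43 in controls and 5.98 in knockouts, below the array medians of 7.25 and 7.34. When adjusted over the list alone 2 rose and 2 fell, and the list was not called (camera adjusted p = 0.951). Cdkn2a no longer passed with the trend removed (adjusted p = 0.121). NF-kB targets had 1 of 19 higher, Ier3 (0.28), and 2 lower, Traf1 (−0.30) and Cflar (−0.28), the same counts when adjusted over the list alone, and a median of 0.01 while the test pointed lower (camera adjusted p = 0.199). The immediate early and stress response list had 1 of 19 genes higher and 3 lower, Jund (−0.49) and Hspa8 (−0.33) among the latter, or 2 and 4 when adjusted over the list alone (camera adjusted p = 0.133). Of 21 type I interferon response genes 4 rose, among them Rtp4 (0.36), Ddx58 (0.34) and Oas2 (0.28), or 5 when adjusted over the list alone, and none fell (median 0.16, camera adjusted p = 0.0908). The interferon list was called higher without control replicate 5 (median 0.19) or knockout replicate 1 (median 0.18). Rtp4, Oas2, Ier3 and Hspa8 no longer passed with the trend removed.

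**Figure D3:**
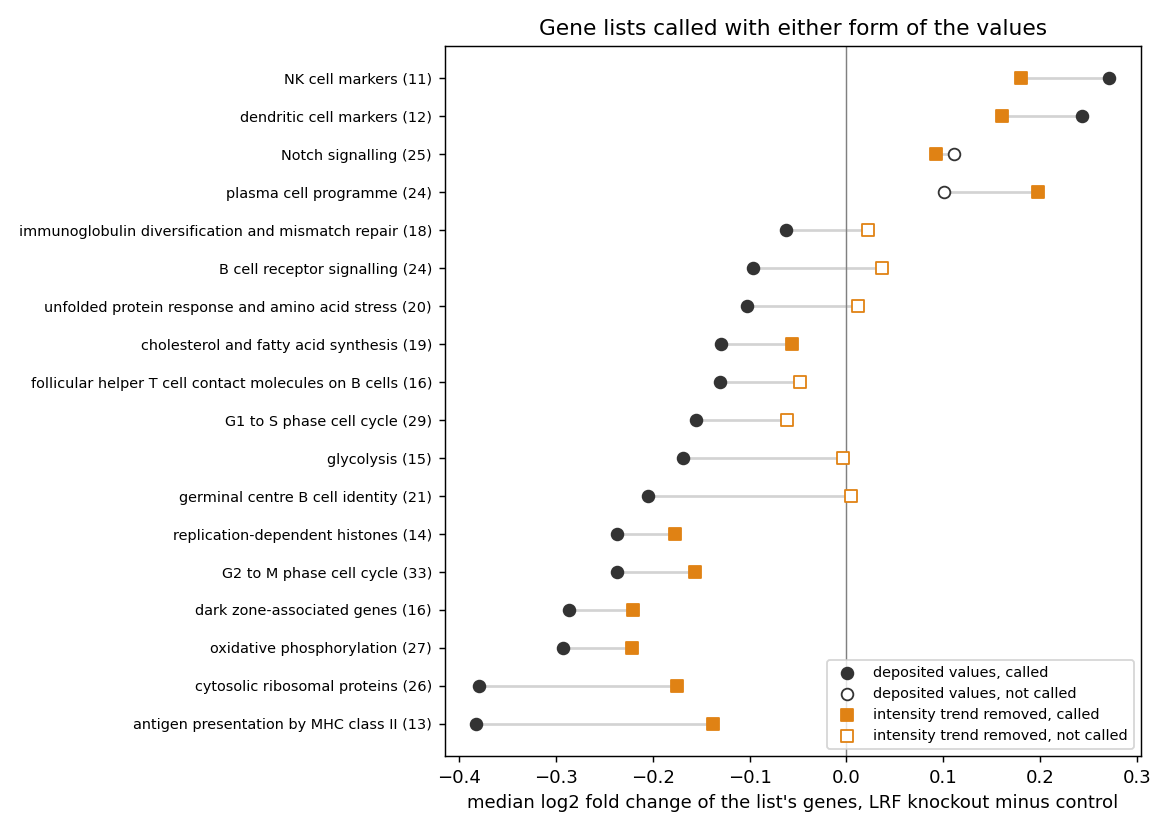
Median log2 fold change of the genes of each list, LRF knockout minus control (horizontal axis), for the 18 lists called on the deposited values or with the intensity trend removed (vertical axis, number of measured genes in brackets). Filled symbols are lists called by camera at a preset correlation of 0.01 and open ones are not. Ribosomal protein genes lie at −0.38 and −0.18 and germinal centre identity genes at −0.20 and 0.00, on the deposited values and with the trend removed.

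Markers of other cell types moved differently from list to list. NK cell markers were higher at a low level: 5 of 11 rose (7 when adjusted over the list alone), with Klrd1 at 0.39, Gzmb at 0.32, Gzma at 0.31 and Ncr1 at 0.30, and the list mean was 5.99 ± 0.03 in controls and 6.22 ± 0.04 in knockouts (SD, n = 4 each). The list was called higher (camera adjusted p = 0.00342; adjusted p = 0.282 with an estimated correlation; 0.0172 with the trend removed), where Klrd1 passed and Gzmb, Gzma and Ncr1 did not. Of 12 dendritic cell markers, 4 rose, among them Itgax (0.51), Cd209a (0.47) and Ccr9 (0.37), and Flt3 fell (−0.53). This list was called higher (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0283; adjusted p = 0.311 with an estimated correlation; 0.0172 with the trend removed). Monocyte and macrophage markers moved apart. Of 21, 5 rose and 3 fell, also when adjusted over the list alone. Itgam, the integrin CD11b, had 0.79 (SE 0.12, adjusted p = 0.00173) and Lyz2 0.96, while Slc40a1, the iron exporter ferroportin, had −0.69 (SE 0.15, adjusted p = 0.0111). Tyrobp (0.46), Mpeg1 (0.36) and Fcer1g (0.35), which rose, and Hmox1 (−0.51) and Apoe (−0.44), which fell, are named after their values were seen. Of the 8, Tyrobp, Fcer1g, Hmox1 and Apoe no longer passed with the trend removed. The median of that list was −0.02 and its mean 0.02, with the test pointing lower and no call (camera adjusted p = 0.42). Control replicate 3 stood apart, with a list mean of 8.72 against 8.17 to 8.28 on the other controls. Without it the median was 0.07 and the mean 0.14, and the test pointed higher, also without a call (camera adjusted p = 0.244).

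T cell markers had 4 of 18 higher, with Cd28 at 0.48 and Cd247 at 0.27, and 1 lower, Cd2 at −0.75, which B cells also express, the same counts when adjusted over the list alone (camera adjusted p = 0.133). The T cell list was called higher without control replicate 1 (median 0.14). Of 14 neutrophil markers Csf3r alone rose (0.34), also when adjusted over the list alone, while Elane (0.16, adjusted p = 0.128) and S100a9 (0.16, adjusted p = 0.195) did not pass (camera adjusted p = 0.144). Stromal and follicular dendritic cell markers had 2 of 15 higher, Madcam1 (0.59) among them, and 3 lower, including Cr1l and Vim (both −0.39), or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.951). Cd28, Csf3r and Vim no longer passed with the trend removed. Of 16 globin and erythroid genes Hbb-bh1 alone passed, as lower from a low control level of 6.43, also when adjusted over the list alone. Hba-x (0.27, adjusted p = 0.0517) and Ermap (0.32, adjusted p = 0.081) did not. This list mean was 7.60 ± 0.05 in controls and 7.76 ± 0.40 in knockouts (SD, n = 4 each), with knockout replicate 2 at 8.35, and the list was not called (camera adjusted p = 0.337). Xist was high and the Y-linked genes Eif2s3y, Kdm5d and Uty low on 1 array of each group, control replicate 5 and knockout replicate 4, so that both groups held 1 array of that kind.

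**Figure D4:**
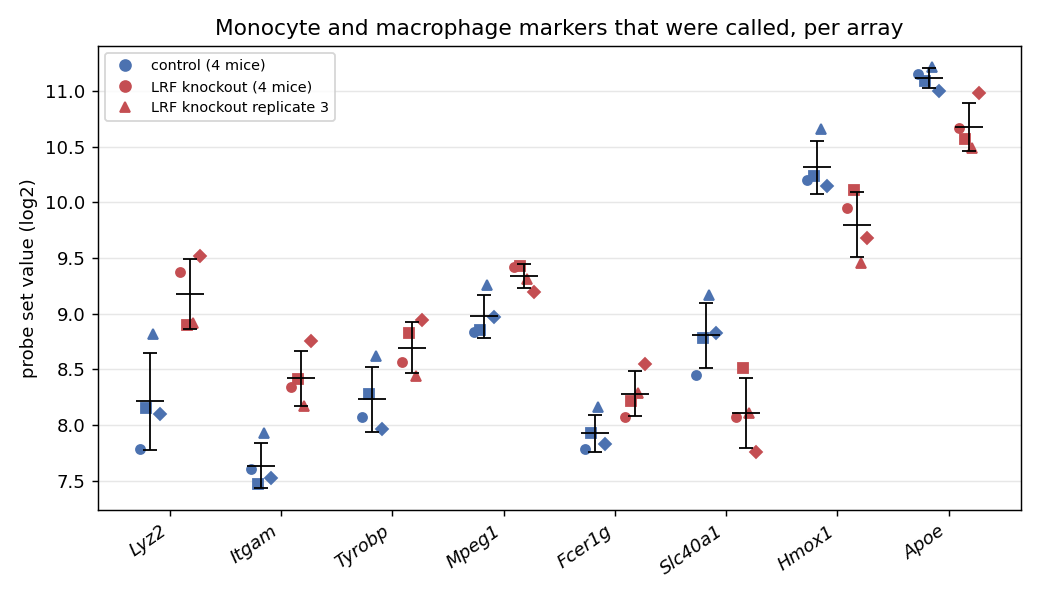
Probe set values (log2, vertical axis) of the 8 monocyte and macrophage markers that passed the test (horizontal axis) on the 4 control and 4 LRF knockout arrays; points are single mice, bars are mean and SD. The 5 genes on the left were higher in knockouts, as Lyz2 with means of 8.21 and 9.17, and the 3 on the right were lower, as Slc40a1 with a log2 fold change of −0.69.

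The neighbourhood of Zbtb7a on chromosome 10 was examined because the groups differ in copies of the targeted allele on a mixed background. Within 10 Mb of Zbtb7a, 53 of 294 genes changed (18.0%), 21 higher and 32 lower, against 2721 of 19561 other genes (13.9%). The odds ratio was 1.36 and the difference did not pass the threshold (two-sided Fisher's exact p = 0.0507). Within 5 Mb, 44 of 222 genes changed (19.8%), with an odds ratio of 1.53 that did pass (Fisher's exact p = 0.0147). Within 20 Mb it was 1.18 (Fisher's exact p = 0.219), and with genes counted at an unadjusted p under 0.05 within 10 Mb it was also 1.18 (Fisher's exact p = 0.19). With the intensity trend removed, 29 of the 294 genes within 10 Mb changed (9.86%) against 8.26% of the others, and 20 of the 222 within 5 Mb (9.01%) against 8.27% (odds ratio 1.10, Fisher's exact p = 0.713).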

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

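The tests of the narrowed value range were chosen after the results were seen; the splits of the arrays were planned. The real grouping called 2784 genes and the highest of the other splits called 0, so that 1 of the 35 splits of the 8 arrays gave as many. This is the smallest share the design allows (0.0286). It lies under the threshold of 0.05, which argues against chance without excluding it. The other splits mix the genotypes in each group, which adds to their spread, so their count of 0 is no measure of how many calls are false. Nor can the splits tell genotype from a technical difference that ran with the groups.

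A narrowed value range of the knockout arrays was examined as a source of the list shifts. The span without the lowest 10% and the highest 10% of values was 4.61 to 4.69 on knockout replicates 1, 2 and 4. It was 4.80 on knockout replicate 3 and 4.77 to 4.87 on controls. This narrowing did not pass the threshold between the groups (exact permutation p = 0.0857, and 0.0571 for the SD of the values). The tables argue against it as the whole cause for the oxidative phosphorylation and ribosomal protein lists, whose mean differences with the trend removed, −0.20 (9.44 ± 0.05 to 9.23 ± 0.07) and −0.16 (10.81 ± 0.07 to 10.65 ± 0.09), exceeded their spread, with a highest camera adjusted p of 0.000752 at the preset correlation, although with an estimated correlation neither list was called (adjusted p = 0.515 and 0.673); a lower level in cells without LRF stays open there, as does a technical cause other than the range. For the G2 to M phase list that p was 0.000204, but knockout replicate 3 had a mean of 9.38 inside the controls, so range and genotype cannot be told apart. For the germinal centre identity and B cell receptor lists the lowest p was 0.745 and the mean differences of −0.21 (10.61 ± 0.02 to 10.39 ± 0.08) and −0.16 (10.35 ± 0.03 to 10.19 ± 0.07) became −0.03 (10.52 ± 0.03 to 10.48 ± 0.03) and −0.00 (10.27 ± 0.04 to 10.27 ± 0.02), so the calls ended because the difference shrank, and the narrowed range may account for them. The test for these lists used that p alone, without the mean of knockout replicate 3 used for the other lists. Knockout replicate 3 had means of 10.51 and 10.27, below the lowest controls at 10.59 and 10.32. By the rule of the other lists, range and genotype could not be told apart here. The genes that passed with the trend removed went both ways, 1 higher and 1 lower in the identity list and 3 higher and 4 lower in the receptor list.

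Single arrays lay apart from the other 3 of their group in 29 of 354 sets of 4 values, against 17.7 expected at 1 in 20. The 29 include sets of the sex-linked transcripts described below. The list means also contain named genes, so the sets are not independent and the excess is not tested. The measure is the gap to the nearest array divided by the group's range, printed where it passed the critical value of Dixon's test. Control replicate 2 was high for Tmeff1 (0.911), H2-Aa (0.837), H2-Ab1 (0.890) and Phgdh (0.840) and in the plasma cell (0.897) and oxidative phosphorylation (0.855) list means, and low for Notch3 (0.933) and the marginal zone and B-1 list mean (0.830). Control replicate 1 was high for Bak1 (0.852), and control replicate 3 was high for Gzma (0.889) and low for Cd247 (0.845). Knockout replicate 2 was low for Rpl7 (0.911), Uqcrc1 (0.890) and the ribosomal protein list mean (0.837), and knockout replicate 4 was low for Tmeff1 (0.870) and Asns (0.896). Knockout replicate 3 was high for Zc3h12c (0.862), Osbpl9 (0.835), Rrm1 (0.836) and the list means of the G1 to S phases (0.848) and immunoglobulin diversification (0.881), and low for the stromal list mean (0.922).

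Xist was high on control replicate 5 (10.14, measure 0.954) and knockout replicate 4 (9.59, 0.971). Eif2s3y was low on the same arrays (0.945 and 0.911), as was Kdm5d (0.960 and 0.875), and Uty was low on control replicate 5 (0.846). With these arrays as a block, 2382 genes changed and 16 lists were called.

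Probe sets outside the gene analysis also changed when every probe set was tested singly: 322 of the 12146 not listed with a gene (2.65%; 154 higher and 168 lower) and 101 of the 1621 with several symbols (8 higher and 93 lower), against 4.28% of those with 1 symbol.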

How the results depend on the processing

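The tests with the intensity trend removed, with the Xist-high arrays as a block and with knockout replicate 3 alone were chosen after the values were seen. Zbtb7a stayed lower and past the threshold in every setting except knockout replicate 3 alone (−0.48, not past it), and over the arrays left out singly it ranged from −0.56 to −0.48. Signal over background was not available, and the number of arrays limits what small changes can be found.

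The total of 2784 changed genes (1312 higher, 1472 lower) was 1611 (706 and 905) with quantile normalization again, 4716 (2594 higher) with array weights, 551 (206 and 345) with the replicate block, 4906 (2735 higher) at an adjusted p under 0.10, 1652 (682 and 970) with the trend removed and 1356 (470 and 886) with every probe set tested singly. With arrays centred on their medians 401 were higher and 2334 lower. The block keeps 6 arrays and the threshold of 0.10 admits more genes by construction; for the other settings the cause was not tested. With knockout replicate 3 alone against the controls 16 genes passed (11 and 5; 2065 at an unadjusted p under 0.05), where 1 array is assumed to vary like the controls. Leaving out 1 array gave 1149 to 5350 changed genes, 442 to 3027 higher and 707 to 2323 lower, each time lowest without knockout replicate 2 and highest without knockout replicate 3.

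Of the 34 lists 16 were called, 15 to 19 with 1 array left out, 0 with an estimated correlation (smallest adjusted p 0.282) and 0 with the trend removed and an estimated correlation (smallest 0.515). At a preset correlation of 0.05, 14 were called, without the immunoglobulin diversification and dendritic cell lists. With fry, which asks whether a list's genes move one way and does not compare them with other genes, 11 passed, 9 of them among the 16. The lists of G2 to M (adjusted p = 0.0772), G1 to S (0.162), histones (0.0607), glycolysis (0.0625), follicular helper T cell contact (0.0772), unfolded protein response (0.0772) and immunoglobulin diversification (0.35) did not pass it, and p53 targets (0.0121) and marginal zone and B-1 genes (0.0274) did. With the trend removed, with either correlation, the B cell receptor list had a median of 0.036 and the glycolysis list one of −0.0039, each with the test's direction reversed. With knockout replicate 3 alone the immunoglobulin diversification list (0.075) and the globin list (−0.072) reversed, and the medians of G2 to M (0.018), G1 to S (0.00055), MYC-driven ribosome biogenesis (0.076) and stromal markers (−0.059) also changed sign, with none of these 4 called there. The cause was not tested. Around Zbtb7a the odds ratio of 1.36 became 1.53 and passed the threshold with the 5 Mb window, and became 1.18 with the 20 Mb window and with an unadjusted p, neither past it. Among the single genes and lists, 2753 values under the alternatives kept direction and side of the threshold, 529 no longer passed, 45 newly passed and 6 reversed.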

Other observations

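The gene families, the removal of the intensity trend and the comparison of the inner with the outer region around Zbtb7a, and the draws and regions for its 5 Mb window, were chosen after the values were seen, as were the monocyte genes named singly and the arrays left out for them; the predictions for the monocyte lists were written before their test. Families of genes that share a symbol stem and have at least 15 measured members, 131 in all, were tested like the lists. With the intensity trend removed 10 were called, 31 without its removal, all 10 in the same direction under both, after quantile normalization applied again and after centring on medians, and 0 with an estimated correlation (adjusted p = 0.84). Genes of the mitochondrial ribosome were lower: 15 of 48 Mrpl genes fell and none rose (median −0.19, also with the trend removed, adjusted p = 5.28e-07), and 8 of 29 Mrps genes fell and 2 rose (adjusted p = 0.0113 with the trend removed). Of 46 Psm genes, most of which encode proteasome subunits, 20 fell and none rose (median −0.27, and −0.18 with the trend removed, adjusted p = 1.93e-06), and of 49 Eif genes, of translation initiation, 15 fell (0.0139).

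Collagen genes were higher: 9 of 44 Col genes rose and none fell, with medians of 0.20 and, with the trend removed, 0.15 (adjusted p = 1.04e-06). Their median on knockout replicate 3 was 0.03 above the controls. Of 20 Tnfrsf genes, receptors of the tumour necrosis factor family, 4 rose and none fell (adjusted p = 0.0404 with the trend removed). Of 291 Mir genes 31 rose and 3 fell (0.0139), at a mean level of 6.11, and of 30 Snx genes, sorting nexins, 10 fell and 2 rose (0.0283). The Rpl and Rps families, of the cytosolic ribosome, were lower too (0.00116 and 0.00371).

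Lyz2, Itgam and other myeloid genes rose while other macrophage markers fell, and monocytes among the sorted knockout cells may be a source. The cells were gated on B220 and CD19, and how fully this removed monocytes was not tested. All 16 genes of a non-classical monocyte list were measured: their median with the trend removed was 0.184 (camera p = 0.00466; p = 0.21 with an estimated correlation), below the 0.2 predicted, with Cx3cr1 higher (0.41), Lst1 at 0.07 and Gngt2 lower (−0.48), all with the trend removed. For the 13 measured of 16 classical monocyte genes the median was 0.193 (camera p = 0.000992; p = 0.0158 with an estimated correlation), also below it, with Ms4a6c higher (0.59, trend removed). None of the measured genes stands in another list, and their median level in controls was 7.88 and 7.13 on the log2 scale, with Gngt2 (9.84) and Ms4a6c (9.28) highest, so that the sorted cells or the background already gave signal for them. Control replicate 3 was high for many of these genes (Sirpa 9.60, Fn1 8.89) and without it the medians were 0.236 and 0.226, past 0.2; with another array left out they were 0.126 to 0.197 and 0.135 to 0.215, past 0.2 in the classical list without knockout replicate 1 (0.2005) or 3 (0.215), so neither kind of monocyte is excluded, and expression by the B cells themselves was not tested.

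More genes changed within 5 Mb of Zbtb7a than elsewhere, a difference that did not pass the threshold within 10 or 20 Mb, nor within 5 Mb with the trend removed (9.01% against 8.27%, Fisher's exact p = 0.713). Among 10000 draws of genes of like expression, a share of 0.212 had as many changed genes as the 53 within 10 Mb, and a share of 0.0833 of the 84 regions of 20 Mb (7 regions) had as high a share, so expression level and variation between regions could each account for the share in that window. For the 5 Mb window, a share of 0.115 of the draws had as many as its 44, and 2 of 67 regions of 10 Mb had as high a share (0.0299, its own region included), on the deposited values only, so neither is settled for it. Strain variants linked to the targeted allele stay open: within 2 Mb 30 of 139 genes changed (21.6%) against 12 of 111 (10.8%) between 10 and 20 Mb (one-sided Fisher's exact p = 0.0171), but 12 (8.63%) and 7 (6.31%) with the trend removed (p = 0.329).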
